A study of Homo sapiens with 30 samples.

How the data were processed

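HepG2 cells, a line derived from a human liver tumour, were treated for 24 h with ethanol extracts of 4 traditional multi-herb formulas or with vehicle, and messenger RNA was sequenced in 30 libraries. Per the labels' protocols, total RNA with a RIN above 7 went into a directional MGIEasy mRNA library preparation and was sequenced on an MGIseq instrument as paired-end reads of 100 bp. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a, RSEM 1.3.3 and the build hg38 (GRCh38), without stating the role or order of each. The annotation release and the strand setting are not given. The deposited table was read as RSEM expected counts per gene, not scaled, for 60675 gene IDs in 30 sample columns: its values are in part not whole and its column totals are unequal. The 30 empty columns at its end were not used. The series text says that libraries without usable results from low RNA concentration were left out before deposit, and it names wortmannin as a positive control, which is not analysed here. It also allows lower concentrations for extracts with stronger toxicity. The doses used here are those of the sample labels.

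Expected counts were rounded to whole numbers. Gene IDs were matched by identifier: 56558 to a gene name table and 497 more to GENCODE 29 only, while 3620 stayed without a name. GENCODE 29 on GRCh38 gave coordinates for 57055 IDs, and each named gene's position is given 1-based on that build. Levels are CPM of the library size after TMM normalisation, with the SD between libraries. Libraries held 19356994 to 25229352 counts.

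Comparisons used edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, robust dispersions, quasi-likelihood F test, two-sided) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fit A held the 21 libraries of vehicle, Soshiho-tang and Yijin-tang with group means, 11 comparisons and 15428 genes. Fit B held the 9 libraries of vehicle and Okbyeongpung-san with the batch letter of the title as a term, 3 comparisons and 15360 genes. Soyo-san, with 1 library per dose, was reported as log2 ratios with a prior count of 1 and 95% intervals from counting error, without a test. Changes are log2 fold changes with their SE from the fit.

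Before the data were examined, 32 gene lists with 486 entries, the comparisons, the alternatives and the rule for named genes were fixed. Lists with 3 or more tested genes were tested with camera (limma 3.58.1) at its preset correlation of 0.01 on voom values, two-sided, adjusted over all lists and comparisons of a fit. Camera with an estimated correlation and fry stood beside it. Some genes, such as NQO1, SLC7A11 and ABCC2, stand on 2 lists, so calls of different lists are not independent. For Soyo-san each list median was placed among 10000 random lists matched on expression. The named genes were a fixed set (CYP1A1, HMOX1, CYP3A4, DDIT3 and ALB), up to 2 members per list with the lowest adjusted p at 500 µg/mL, and the genes with the largest change in each direction (5 at 500 µg/mL and 3 at the lower doses) with at least 5 CPM, a gene symbol and no overlap between the libraries of the groups. The rule took up to 3 members per list unless a comparison then gave more than about 30 genes, which it did. Of the genes the rule selects, 2 are not reported here. Values of the others are also given for 500 against 20 µg/mL and for the lower doses.

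The scripts were tested on simulated counts. With 100 genes changed by 0.5 on the log2 scale and 100 by 1 among 15241 genes, the fit for Soshiho-tang at 500 µg/mL against vehicle recovered 83% and 100%, with 12 false calls (6.15% of calls). The fit for Okbyeongpung-san at 500 µg/mL recovered 79% and 97% among 15158 genes, with 17 false calls (8.81%). In both, the changed genes were drawn only from genes above a minimum count, so the recovery does not cover genes with low counts.

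Alternatives were no filter on low counts, DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, a fit of only the groups compared, the replicate number as a block, each library left out in turn, and for Okbyeongpung-san no batch letter or the batch E library alone. Added after the data were seen were an offset per library for the GC content of the longest transcript (a natural spline with 5 df), the same with transcript length, the replicate block with the GC offset, and list tests without replicate 3 of Yijin-tang at 500 µg/mL. Correlations across genes treat genes that are not independent replicates. Principal components were computed on log2 CPM of 13107 genes with a mean above 1 CPM.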

Results

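Gene expression was measured in HepG2 cells after 24 h with Soshiho-tang, Yijin-tang, Okbyeongpung-san or Soyo-san, 4 traditional East Asian formulas of several herbs each, or with vehicle. The vehicle was DMSO, given as 0.1% in the sample labels and as 2% in the series text. Vehicle and each of the doses 500, 100 and 20 µg/mL of Soshiho-tang and Yijin-tang had 3 libraries, all titled batch E. Okbyeongpung-san had 2 libraries per dose, 1 titled batch E and 1 titled batch D, and Soyo-san had 1 library per dose, titled batch D. Libraries held 19356994 to 25229352 counts, with 20441904 to 24734966 in vehicle. Nothing in the labels says that the replicates came from separate cultures. Gene list calls printed with a single adjusted p also passed with an estimated correlation.

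The vehicle libraries stood apart from all 27 treated libraries, whatever the formula and dose. On the first principal component, with 25.2% of the variance, they lay at -35.1 to -32 and the treated libraries at -5.55 to 16. The 13 genes of the mitochondrial genome, which encode parts of the respiratory chain, took 13.3% ± 1.61 of the counts in vehicle (SD, n = 3; 12.2 to 15.1) and 8.4% to 12.9% in the treated libraries. With Soshiho-tang at 20 µg/mL, the 10% of genes with the lowest GC content (median 36.9%) had a median log2 change of 0.253 against vehicle. The 10% with the highest (64.2%) had a median of -0.298. The correlation across genes of GC content with the change against vehicle was -0.46 at 500 and -0.565 at 20 µg/mL of Soshiho-tang. For 500 against 20 µg/mL it was -0.0191 in Soshiho-tang and -0.0062 in Yijin-tang. Changes between doses and between formulas are therefore given beside those against vehicle, for Okbyeongpung-san between doses as list medians only.

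**Figure D1:**
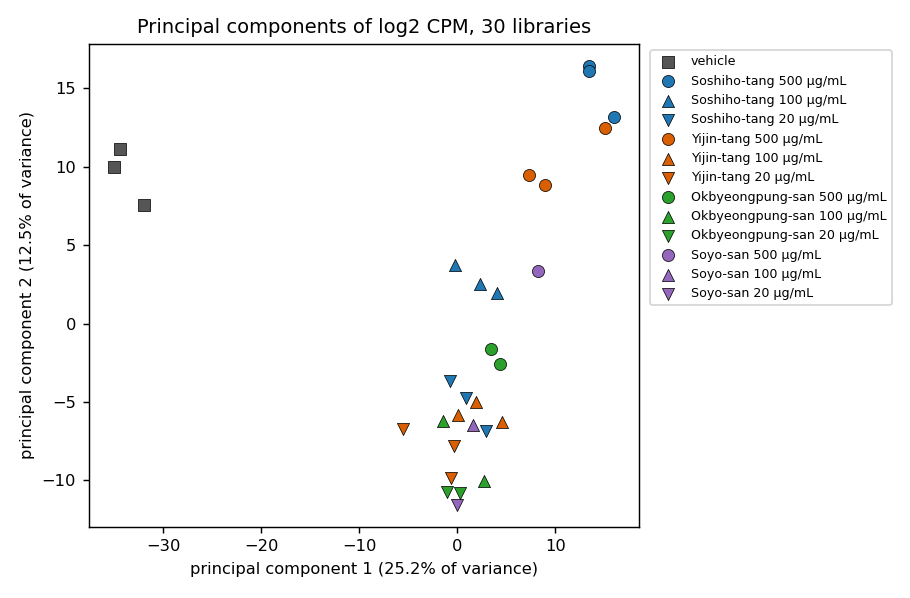
Principal components 1 and 2 of log2 CPM, with the percent of variance on each axis; 1 point per library, marked by group. The 3 vehicle libraries lie at -35.1 to -32 on component 1 and the 27 treated libraries at -5.55 to 16.

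**Figure D2:**
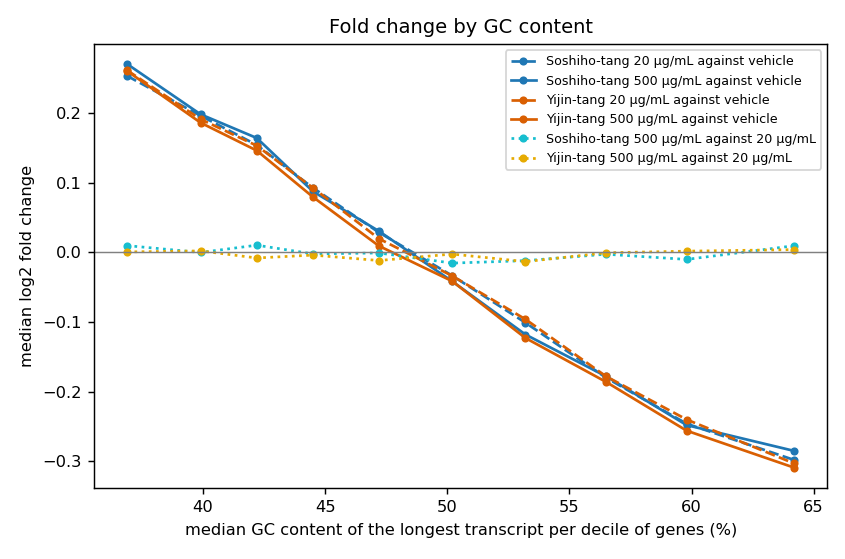
Median log2 fold change of genes in 10 bins of GC content of the longest transcript, for comparisons with vehicle and for 500 against 20 µg/mL. The changes against vehicle fall from low to high GC content (0.253 to -0.298 for Soshiho-tang at 20 µg/mL), and those between doses stay flat.

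Soshiho-tang raised genes of xenobiotic metabolism and of the antioxidant response and lowered genes of sterol and fatty acid synthesis as its dose rose. CYP1A1, a cytochrome P450 that oxidises aromatic compounds and a classic target of the aryl hydrocarbon receptor (AhR), was at 8.07 ± 0.798 CPM in vehicle and at 58.3 ± 15.5, 247 ± 14.1 and 715 ± 20.4 CPM at 20, 100 and 500 µg/mL (SD, n = 3 each). AKR1B10, an aldo-keto reductase that the antioxidant regulator NRF2 turns on, was at 39.6 ± 3.78 CPM in vehicle, 64.2 ± 1.93 at 20 and 247 ± 6.99 at 500 µg/mL. FADS2, a fatty acid desaturase, was at 318 ± 16.2 CPM in vehicle, 264 at 20 and 182 ± 1.57 at 500 µg/mL. From 20 to 500 µg/mL the log2 changes were 3.62 ± 0.126 (SE; adjusted p = 9.57e-12), 1.95 ± 0.0477 (adjusted p = 1.91e-24) and -0.54 ± 0.0404 (adjusted p = 6.99e-12). CYP1A1 lies on chromosome 15 at 74719542 to 74725610 (minus strand), AKR1B10 on chromosome 7 at 134527592 to 134541408 (plus strand) and FADS2 on chromosome 11 at 61792980 to 61867354 (plus strand).

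Soshiho-tang at 500 against 20 µg/mL changed 2641 of 15428 genes (1381 higher, 1260 lower), of which 132 moved at least 2-fold. Of the 7 AhR targets measured, 6 rose and 1 did not pass (6 rose adjusted over the list alone; median log2 2.39, camera adjusted p = 5.76e-10). Of 19 NRF2 targets, 18 rose and 1 did not pass (19 rose adjusted over the list alone; median 0.93, adjusted p = 2.21e-46). They included NQO1, a quinone reductase (1.04 ± 0.04), SLC7A11, the cystine importer that feeds glutathione synthesis (1.20 ± 0.0553). HMOX1, which breaks down heme, rose with them (0.64 ± 0.0525, adjusted p = 5.28e-11). The integrated stress response list, genes that ATF4 turns on when translation is held back, had 11 of 20 higher and 9 that did not pass (11 adjusted over the list alone; median 0.22, adjusted p = 9.09e-12). GDF15, a secreted stress signal, rose by 1.19 ± 0.0545 and MTHFD2, a mitochondrial folate enzyme, by 0.36 ± 0.0466. DDIT3, the stress factor CHOP, was at 0.11 (adjusted p = 0.452). Of 10 targets of the drug receptors PXR and CAR, 5 rose and 5 did not pass (5 adjusted over the list alone; median 0.25, adjusted p = 0.000335). ABCC2 among them, an export pump for conjugates that is also on the NRF2 list, rose by 0.93 ± 0.0522. CYP3A4, the main drug-metabolising target of PXR, stayed below the filter for testing, with 0.179 CPM at 500 µg/mL and 0.142 ± 0.0372 in vehicle.

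Genes of lipid synthesis and of liver secretion moved the other way in the same comparison. Of 23 genes of cholesterol synthesis and uptake, 20 fell and 3 did not pass (21 fell adjusted over the list alone; median -0.29, adjusted p = 2.63e-21). LSS, lanosterol synthase, was at -0.36 ± 0.043 (adjusted p = 1.64e-07). Of 14 genes of fatty acid synthesis, 10 fell and 4 did not pass (12 fell adjusted over the list alone; median -0.26, adjusted p = 5.35e-12). FADS2 was at -0.54 ± 0.0404 and ACSS2, which makes acetyl-CoA from acetate, at -0.54 ± 0.0461. CPT1A, the enzyme that admits fatty acids to mitochondria, rose by 0.89 ± 0.0641. Its list of fatty acid oxidation genes had 4 of 18 higher and 4 lower and was not called (5 higher and 5 lower adjusted over the list alone; median -0.0041, mean 0.0146, adjusted p = 0.801). Of 14 acute phase proteins, 1 rose, 9 fell and 4 did not pass (1 and 9 adjusted over the list alone; median -0.27, adjusted p = 4.33e-09). Of 18 genes of hepatocyte identity, 12 fell and 6 did not pass (13 adjusted over the list alone; median -0.25, adjusted p = 1.96e-09). The fibrinogen chains FGA and FGB fell by 0.68 ± 0.037 and 0.52 ± 0.0496, and ALB, serum albumin, by 0.22 ± 0.0437 (adjusted p = 0.000314). Of 20 mitosis genes, 12 fell and 8 did not pass (17 fell adjusted over the list alone; median -0.16, adjusted p = 3.92e-09). Of 18 chaperones of the endoplasmic reticulum, 8 fell and 10 did not pass (1 rose and 10 fell adjusted over the list alone; median -0.12, adjusted p = 0.000386).

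Further named genes changed from 20 to 500 µg/mL of Soshiho-tang. SOS1, an exchange factor that activates RAS, was at 103 ± 8.14 CPM in vehicle, 132 ± 10 at 20 and 493 ± 17.7 at 500 µg/mL (1.91 ± 0.0703 for 500 against 20, adjusted p = 4.16e-15). SOS1-IT1, a transcript annotated inside SOS1 on the same strand (chromosome 2, 38992279 to 38993857 within 38981396 to 39124345), rose by 1.88 ± 0.159, and its counts cannot be separated with certainty from reads of SOS1. IGFBP1, an insulin-regulated binding protein secreted by liver, was at 39.6 ± 3.79 CPM at 20 and 136 ± 46.1 at 500 µg/mL (1.78 ± 0.223, adjusted p = 3.9e-05). DKK1, a secreted inhibitor of WNT signalling, was at 88.6 ± 2.01 CPM at 20 and 45.1 at 500 µg/mL (-0.97 ± 0.0511, adjusted p = 1.2e-15). SLC6A12, a betaine transporter, fell by 1.39 ± 0.19 and NGFR, a nerve growth factor receptor, by 0.67 ± 0.152, both from levels under 10 CPM.

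Against vehicle, Soshiho-tang at 500 µg/mL raised CYP1A1 88.6-fold (log2 6.47 ± 0.159, adjusted p = 4.15e-14), AKR1B10 by 2.64 ± 0.0501, NQO1 by 1.64 ± 0.0408 and GDF15 by 1.67 ± 0.0559. It lowered FADS2 by -0.81 ± 0.0404 and TNS4, a focal adhesion protein, by -1.44 ± 0.0716. In all, 8002 genes changed at 500 µg/mL (4116 higher, 3886 lower), 6882 at 100 (3529 and 3353) and 6662 at 20 (3407 and 3255), with 499, 251 and 167 of them at least 2-fold. At 20 µg/mL CYP1A1 was already up by 2.85 ± 0.167 and AKR1B10 by 0.69 ± 0.052. At 500 µg/mL ALB stood at 0.08 (adjusted p = 0.13), a value that turned negative with a GC offset (-0.082). DDIT3 was higher than vehicle at every dose, by 0.45 ± 0.0958 at 20 and 0.56 ± 0.0942 at 500 µg/mL (8.45 and 9.1 CPM against 6.15).

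The gene lists against vehicle showed the same leading groups. At 500 µg/mL all 7 AhR targets rose (7 adjusted over the list alone; median 2.08, adjusted p = 7.81e-06) and 17 of 19 NRF2 targets rose and 2 did not pass (18 adjusted over the list alone; median 0.84, adjusted p = 1.62e-17). Likewise 14 of 20 integrated stress response genes rose, 1 fell and 5 did not pass (15 and 1 adjusted over the list alone; median 0.40, adjusted p = 3.4e-06). Cholesterol genes had 4 of 23 higher and 15 lower (4 and 15 adjusted over the list alone; median -0.21, adjusted p = 0.000962, and adjusted p = 0.0862 with an estimated correlation). With a GC offset 0 were higher and 13 lower (median -0.15). Fatty acid synthesis had 13 of 14 lower (13 adjusted over the list alone; median -0.26, adjusted p = 3.24e-06, and adjusted p = 0.12 with an estimated correlation). All of these stood beside 11 of 13 mitochondrial genome transcripts that were lower (11 adjusted over the list alone; median -0.60, adjusted p = 0.000211, and adjusted p = 0.478 with an estimated correlation). Ribosomal protein genes had 15 of 20 higher and 2 lower (16 and 2 adjusted over the list alone; median 0.21, adjusted p = 0.000937, and adjusted p = 0.528 with an estimated correlation). At 20 µg/mL 10 of 13 mitochondrial transcripts were lower (11 adjusted over the list alone; median -0.46, adjusted p = 0.00033, and adjusted p = 0.483 with an estimated correlation). There 3 of 7 AhR targets were higher (4 adjusted over the list alone; median 0.60, adjusted p = 0.00999, and adjusted p = 0.0954 with an estimated correlation). At 100 µg/mL 6 of 7 AhR targets (6 adjusted over the list alone; median 1.04, adjusted p = 3.2e-05) were higher, and 12 of 19 NRF2 targets were higher and 1 lower (14 and 1 adjusted over the list alone; median 0.30, adjusted p = 1.02e-08).

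**Figure D3:**
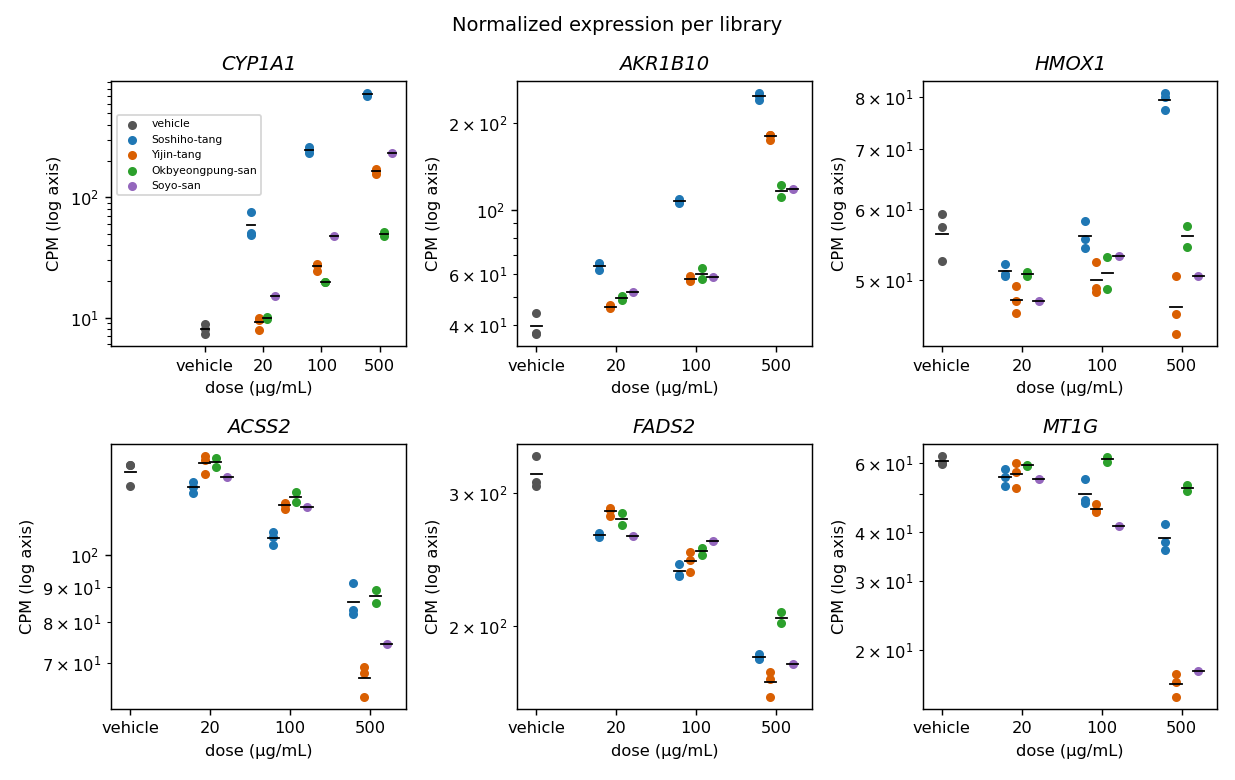
CPM of 6 genes in each library by dose, on a log axis; points are libraries and black bars are group means. CYP1A1 rises from 8.07 CPM in vehicle to 715 in Soshiho-tang and 164 in Yijin-tang at 500 µg/mL, and MT1G falls from 60.9 to 16.4 in Yijin-tang at 500 µg/mL.

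Yijin-tang raised the same 2 leading genes at its highest dose, lowered sterol synthesis genes further and lowered the metallothioneins, small proteins that bind zinc and copper. CYP1A1 was at 9.12 ± 1.02, 26.6 ± 1.95 and 164 ± 8.46 CPM at 20, 100 and 500 µg/mL (SD, n = 3 each), against 8.07 in vehicle. AKR1B10 was at 46.3 ± 0.631 CPM at 20 and 180 ± 4.49 at 500 µg/mL. FADS2 was at 284 CPM at 20 and 168 ± 6.58 at 500 µg/mL. MT1G, a metallothionein on chromosome 16 at 56666731 to 56668065 (minus strand), was at 60.9 ± 1.58 CPM in vehicle, 56.4 ± 4.19 at 20 and 16.4 ± 1.11 at 500 µg/mL. From 20 to 500 µg/mL the log2 changes were 4.17 ± 0.155 for CYP1A1 (SE; adjusted p = 4.03e-11), 1.95 ± 0.0491 for AKR1B10, -0.76 ± 0.0405 for FADS2 and -1.78 ± 0.0695 for MT1G (adjusted p = 8.21e-19).

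Yijin-tang at 500 against 20 µg/mL changed 2925 of 15428 genes (1592 higher, 1333 lower), of which 110 moved at least 2-fold. Of 23 cholesterol genes, 21 fell and 2 did not pass (21 adjusted over the list alone; median -0.49, adjusted p = 8.69e-36). LSS was at -0.72 ± 0.0433 (adjusted p = 6.29e-14). All 14 genes of fatty acid synthesis fell (14 adjusted over the list alone; median -0.38, adjusted p = 1.05e-19). ACSS2 was at -1.03 ± 0.0468 and FADS2 at -0.76 ± 0.0405. All 8 genes of the metallothionein list fell (8 adjusted over the list alone; median -1.19, adjusted p = 1.62e-17). MT1F was at -1.99 ± 0.0881, MT2A at -1.03 ± 0.0952 and SLC30A1, a zinc exporter, at -0.44 ± 0.0461. The metallothionein genes are near copies that share reads, so the split between them is uncertain. Of 19 NRF2 targets, 16 rose and 3 did not pass (16 adjusted over the list alone; median 0.48, adjusted p = 1.24e-27). NQO1 was at 0.90 ± 0.0401, while HMOX1 was at -0.03 (adjusted p = 0.743). Of 7 AhR targets, 4 rose and 3 did not pass (5 rose adjusted over the list alone; median 0.90, adjusted p = 4.61e-05). Of 15 glycolysis genes, 12 rose and 3 did not pass (13 adjusted over the list alone; median 0.32, adjusted p = 1.11e-13). LDHA, which makes lactate, was at 0.46 ± 0.0545 and PGAM1, phosphoglycerate mutase, at 0.30 ± 0.0412.

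Of 14 acute phase proteins, 4 rose and 10 fell (4 and 10 adjusted over the list alone; median -0.25, adjusted p = 2.07e-05, and adjusted p = 0.0735 with an estimated correlation). FGA was at -0.53 ± 0.0369. Of 18 genes of hepatocyte identity, 6 fell and 12 did not pass (7 adjusted over the list alone; median -0.075, adjusted p = 0.000971, and adjusted p = 0.231 with an estimated correlation). ALB was at -0.11 (adjusted p = 0.0781). The integrated stress response list was not called, with 3 of 20 higher and 5 lower (median -0.059, adjusted p = 0.51). GDF15 nevertheless rose by 0.80 ± 0.0547, and DDIT3 was at 0.06 (adjusted p = 0.719). IGFBP1 rose by 1.63 ± 0.225 (113 ± 25.9 CPM at 500 µg/mL and 36.5 ± 6.83 at 20), SOS1 by 0.63 ± 0.0709, and SLC39A10, a zinc importer, by 0.83 ± 0.0767 (adjusted p = 1.2e-09). Ribosomal protein genes had 6 of 20 higher and 14 that did not pass (11 higher adjusted over the list alone; median 0.13, adjusted p = 5.57e-05, and adjusted p = 0.466 with an estimated correlation). Replicate 3 at 500 µg/mL stood apart from replicates 1 and 2, its deviations running with transcript length across genes (rho -0.371). Without it 0 ribosomal protein genes passed, 10 of 15 glycolysis genes rose (median 0.26) and the metallothionein median was -1.25. Acute phase proteins then had 1 of 14 higher and 10 lower (4 and 10 adjusted over the list alone; median -0.27, adjusted p = 7.35e-08) and hepatocyte identity 6 of 18 lower (6 adjusted over the list alone; median -0.094, adjusted p = 3.47e-07), both called with an estimated correlation too (adjusted p = 0.00829 and 0.00626).

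Against vehicle, Yijin-tang at 500 µg/mL raised CYP1A1 by 4.34 ± 0.159 (adjusted p = 6.61e-12), IGFBP1 by 2.23 ± 0.238, AKR1B10 by 2.17 ± 0.0501 and NQO1 by 1.25 ± 0.0405. It lowered MT1G by -1.90 ± 0.0693 (adjusted p = 7.86e-20), ACSS2 by -0.99 ± 0.0469 and FADS2 by -0.93 ± 0.0405. At 20 µg/mL AKR1B10 was up by 0.22 ± 0.0533 and NQO1 by 0.34 ± 0.0402, while CYP1A1 was at 0.17 (adjusted p = 0.562). In all, 7983 genes changed at 500 µg/mL (4016 higher, 3967 lower), 7020 at 100 (3571 and 3449) and 6538 at 20 (3312 and 3226), with 408, 192 and 159 of them at least 2-fold. ALB was higher than vehicle at 20 µg/mL (0.39 ± 0.0438) and at 500 (0.28 ± 0.0437, adjusted p = 3.03e-06), the latter becoming 0.037 with a GC and length offset (adjusted p = 0.467). HMOX1 was lower at 500 µg/mL (-0.28 ± 0.0541, adjusted p = 5.41e-05), a call that ended with a GC offset (-0.029, adjusted p = 0.666). DDIT3 was higher at 500 µg/mL by 0.42 ± 0.0951 (adjusted p = 0.000415), and CYP3A4 stood at 0.344 ± 0.397 CPM, below the filter for testing.

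The lists against vehicle at 500 µg/mL had 15 of 19 NRF2 targets higher and 2 lower (15 and 2 adjusted over the list alone; median 0.44, adjusted p = 8.38e-09). They also had 18 of 23 cholesterol genes lower and 1 higher (19 and 1 adjusted over the list alone; median -0.24, adjusted p = 1.96e-08) and 7 of 8 genes of the metallothionein list lower (8 adjusted over the list alone; median -1.24, adjusted p = 1.66e-06). Fatty acid synthesis had 13 of 14 lower (13 adjusted over the list alone; median -0.44, adjusted p = 1.28e-08, and adjusted p = 0.053 with an estimated correlation). AhR targets had 5 of 7 higher (5 adjusted over the list alone; median 0.88, adjusted p = 0.00425, and adjusted p = 0.0653 with an estimated correlation). Glycolysis had 13 of 15 higher (13 higher and 1 lower adjusted over the list alone; median 0.33, adjusted p = 5.23e-05, and adjusted p = 0.317 with an estimated correlation). Cholesterol genes at 20 µg/mL had 10 of 23 higher and 2 lower (10 and 3 adjusted over the list alone; median 0.063, adjusted p = 0.0271, and adjusted p = 0.272 with an estimated correlation). With a GC offset 17 were higher and 0 lower (median 0.155). Mitochondrial genome transcripts were lower beside these, 8 of 13 at 500 µg/mL (8 adjusted over the list alone; median -0.43, adjusted p = 0.0103, and adjusted p = 0.605 with an estimated correlation), 11 of 13 at 100 (11 adjusted over the list alone; median -0.57, adjusted p = 7e-05, and adjusted p = 0.465 with an estimated correlation) and 5 of 13 at 20 (9 adjusted over the list alone; median -0.40, adjusted p = 0.00247, and adjusted p = 0.536 with an estimated correlation). Without replicate 3 of Yijin-tang at 500 µg/mL, 4 of 13 were lower at that dose (4 adjusted over the list alone, median -0.44, adjusted p = 0.0154, and adjusted p = 0.537 with an estimated correlation). Glycolysis then had 10 of 15 higher and 1 lower (median 0.25, adjusted p = 3.68e-05, and adjusted p = 0.169 with an estimated correlation). AhR targets had 5 of 7 higher (median 0.73, adjusted p = 0.00314) and fatty acid synthesis 13 of 14 lower (median -0.36, adjusted p = 2.86e-09), both called with an estimated correlation too (adjusted p = 0.0409 and 0.00529).

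The direct comparison of the formulas at 500 µg/mL asks which responses belong to 1 of them, and it does not rest on the vehicle libraries. Soshiho-tang had more CYP1A1 than Yijin-tang (715 against 164 CPM; 2.13 ± 0.116, adjusted p = 8.4e-09), more SLC7A11 (114 against 57.3 CPM; 1.00 ± 0.0543) and more HMOX1 (79.4 ± 1.76 against 46.6 ± 3.53 CPM; 0.78 ± 0.0526, adjusted p = 3.23e-12). It kept more metallothionein transcript, with MT1G at 38.6 ± 3 against 16.4 CPM (1.24 ± 0.0716, adjusted p = 7.88e-14). It had less TNFSF10, the death ligand TRAIL (5.29 ± 0.666 against 11.4 ± 0.877 CPM; -1.10 ± 0.107, adjusted p = 6.82e-09), less PDGFRB, a growth factor receptor (-0.96 ± 0.105), and less DKK1 (-0.96 ± 0.0509).

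Of 15428 genes, 1239 differed at 500 µg/mL (625 higher and 614 lower in Soshiho-tang), 49 of them at least 2-fold. Of 20 integrated stress response genes, 18 were higher in Soshiho-tang and 2 did not pass (18 adjusted over the list alone; median 0.36, adjusted p = 1e-24). GDF15 was at 0.45 ± 0.0531, MTHFD2 at 0.31 ± 0.0464 and NUPR1, a stress-induced nuclear protein, at 0.94 ± 0.0943, and DDIT3 was at 0.14 (adjusted p = 0.418). Of 19 NRF2 targets 16 were higher (18 adjusted over the list alone; median 0.41, adjusted p = 6.76e-37), and of 7 AhR targets 4 (7 adjusted over the list alone; median 1.29, adjusted p = 1.05e-11). Of 8 genes of the metallothionein list 7 were higher (8 adjusted over the list alone; median 0.84, adjusted p = 1.38e-17), and of 10 PXR and CAR targets 4 (6 adjusted over the list alone; median 0.28, adjusted p = 8.57e-07). Of 23 cholesterol genes 13 were higher in Soshiho-tang (16 adjusted over the list alone; median 0.16, adjusted p = 2.42e-11). LSS was at 0.30 ± 0.0434, whereas FADS2 was at 0.12 (adjusted p = 0.0671). Lower in Soshiho-tang were 12 of 18 endoplasmic reticulum chaperones (16 adjusted over the list alone; median -0.22, adjusted p = 3.51e-17), HYOU1 being at -0.34 ± 0.0394. So were 14 of 20 mitosis genes (16 adjusted over the list alone; median -0.22, adjusted p = 5.75e-14). PLK1, a mitotic kinase, was at -0.25 ± 0.044. Hepatocyte identity had 8 of 18 lower (1 higher and 9 lower adjusted over the list alone; median -0.16, adjusted p = 7.24e-07, and adjusted p = 0.0511 with an estimated correlation). Glycolysis had 4 of 15 lower (1 higher and 6 lower adjusted over the list alone; median -0.079, adjusted p = 0.00167, and adjusted p = 0.456 with an estimated correlation). Ribosomal protein genes had 0 of 20 called (median -0.054, adjusted p = 0.0383, and adjusted p = 0.667 with an estimated correlation). Without replicate 3 of Yijin-tang their median was 0.033 (adjusted p = 0.297). Glycolysis then had 2 of 15 lower (median -0.028, adjusted p = 0.0378, and adjusted p = 0.446 with an estimated correlation), and hepatocyte identity 7 of 18 lower (median -0.12, adjusted p = 2.23e-06, and adjusted p = 0.00896 with an estimated correlation).

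**Figure D4:**
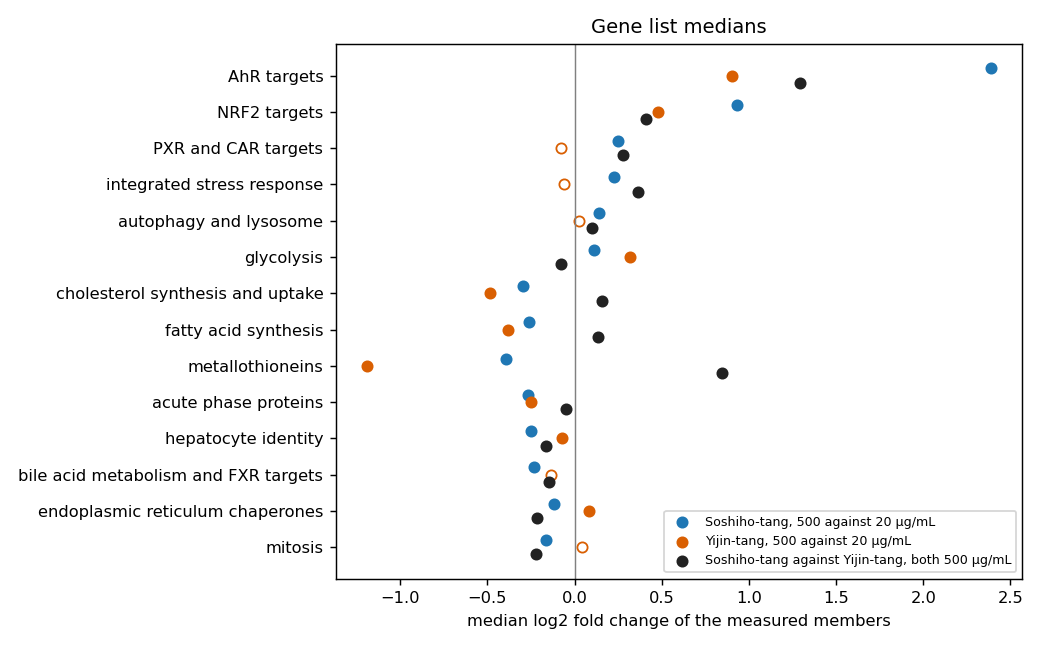
Median log2 fold change of 14 gene lists for Soshiho-tang 500 against 20 µg/mL (blue), Yijin-tang 500 against 20 µg/mL (orange) and Soshiho-tang against Yijin-tang at 500 µg/mL (black); filled points are camera calls at adjusted p under 0.05 with the preset correlation, some of which were lost with an estimated one. The metallothionein list lies at -0.39 (adjusted p = 0.0951 with an estimated correlation), -1.19 and 0.84, and the NRF2 list at 0.93, 0.48 and 0.41.

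At the lower doses the formulas still differed in detoxification genes. At 100 µg/mL, 115 genes differed (81 higher and 34 lower in Soshiho-tang), 11 of them at least 2-fold. Among the named genes CYP1A1 was higher (247 ± 14.1 against 26.6 ± 1.95 CPM; 3.23 ± 0.134, adjusted p = 1.61e-09), as were SOS1 (0.91 ± 0.0706) and AKR1B10 (0.90 ± 0.0488), and DKK1 was lower (-0.41 ± 0.0488). Only 8 genes differed at 20 µg/mL, and 606 had an unadjusted p under 0.05. Of these 8, CYP1A1 (2.68 ± 0.163), AKR1B10 (0.47 ± 0.0511), AKR1C2 (0.28 ± 0.0421, a steroid and aldehyde reductase that shares reads with its near copies) and NQO1 (0.26 ± 0.04, adjusted p = 0.00149) fell under the naming rule. The other genes, SPP1 (0.34), CPLX2 (0.30), ALDH1A1 (0.19) and MATN3 (-0.28), were named after their values were seen. NRF2 targets were called at both doses, with 12 of 19 higher at 100 µg/mL (17 adjusted over the list alone; median 0.31, adjusted p = 1.86e-52) and 3 of 19 at 20 (10 adjusted over the list alone; median 0.12, adjusted p = 3.45e-23). AhR targets were called too, with 5 of 7 higher at 100 (6 adjusted over the list alone; median 1.28, adjusted p = 8.57e-20) and 2 of 7 at 20 µg/mL (3 adjusted over the list alone; median 0.78, adjusted p = 6.06e-11). Cholesterol genes had 1 of 23 lower in Soshiho-tang at 100 µg/mL (4 adjusted over the list alone; median -0.10, adjusted p = 3.04e-10) and 0 of 23 called at 20 (0 adjusted over the list alone; median -0.051, adjusted p = 1.93e-05). With any 1 of the libraries compared left out, 58 to 71 genes differed at 100 µg/mL (lowest without Soshiho-tang replicate 3) and 4 to 7 at 20 (lowest without Yijin-tang replicate 2).

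The formulas shared much of their response between doses. From 20 to 500 µg/mL, 759 genes rose in both formulas (142.5 if the calls were independent), 633 fell in both (109) and 28 moved in opposite directions (249). Among the shared genes were AKR1B10, NQO1, GDF15 and IGFBP1, higher in both, and LSS, FADS2, ACSS2 and FGA, lower in both. The changes correlated across genes with r = 0.27 (rho = 0.459), against -0.0322 in 10 simulations without any effect. Against the shared vehicle at 500 µg/mL, 3371 genes rose in both and 3157 fell in both (1071.4 and 999 if independent), with r = 0.806, where simulated groups without any effect gave 0 calls and r = 0.465. At 20 µg/mL 2883 rose in both and 2794 fell in both, 0 moved in opposite directions and r was 0.774. The correlation with vehicle in common thus contains chance values shared through the same 3 libraries. The simulations held no systematic difference between vehicle and treated libraries. The values against vehicle therefore cannot tell a shared response from a displacement of the vehicle libraries themselves.

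Some named genes changed less from 20 to 500 µg/mL of Soshiho-tang than from vehicle to 20. TMEM160, a mitochondrial membrane protein, was at 1.94 ± 0.655 CPM in vehicle and at 5.55 to 7.29 in the treated groups. DDIT4, an inhibitor of mTOR signalling, rose by 1.35 ± 0.152 at 20 and 1.47 ± 0.15 at 500 µg/mL of Soshiho-tang, and RSRP1, an arginine and serine rich protein, by 1.49 ± 0.0772 and 1.25 ± 0.0783. DEPP1, a FOXO target, was at 26.1 ± 2.29 CPM in vehicle, 10.1 at 20 and 10.2 at 500 µg/mL of Soshiho-tang. TNS4 was at 46.2 ± 3.04 CPM in vehicle and 22.4 ± 1.13 at 20 µg/mL of Soshiho-tang. TUBA1B-AS1, which overlaps a tubulin gene in antisense, had 96.1 ± 55.2 CPM in vehicle and group means of 0 to 7.61 in treated cells. 7SK, a short non-coding RNA gene on chromosome 6, was likewise among the genes with the largest fall against vehicle. This held at every dose of Soshiho-tang, Yijin-tang and Okbyeongpung-san.

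Okbyeongpung-san raised CYP1A1, AKR1B10 and NQO1 too. At 500 µg/mL CYP1A1 was at 49.4 ± 2.86 CPM against 8.07 in vehicle (2.63 ± 0.0867, adjusted p = 2.26e-12; 2 and 3 libraries), AKR1B10 at 117 CPM (1.55 ± 0.0726) and NQO1 at 733 CPM (1.03 ± 0.0458, adjusted p = 1.7e-10). GSTA1, a glutathione transferase, was higher (71 ± 0.269 against 37.1 ± 2.09 CPM; 0.94 ± 0.0657), and ALB was higher than vehicle by 0.37 ± 0.0506. These gene changes are against vehicle, and changes between doses of this formula were not tested per gene. ALB was also higher than vehicle at 20 µg/mL of Yijin-tang and in the single Soyo-san library at 20 µg/mL (log2 ratio 0.401). FADS2 fell by 0.62 ± 0.0525 (adjusted p = 2.79e-07) and ACSS2 by 0.59 ± 0.0569. TAGLN, an actin-binding protein, fell by 0.96 ± 0.103, and TXNIP, which binds thioredoxin and restrains glucose uptake, by 0.77 ± 0.0694. CYP1A1 at 20 µg/mL was at 9.99 CPM (0.32 ± 0.104, adjusted p = 0.0255) and AKR1B10 at 49.7 CPM (0.32 ± 0.0782). Among the fixed genes, HMOX1 was at 0.02 (adjusted p = 0.819) and DDIT3 at 0.31 (adjusted p = 0.0712) at 500 µg/mL, and CYP3A4 stayed below the filter with 0.201 CPM.

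With the batch letter as a term, 5594 of 15360 genes changed at 500 µg/mL (2810 higher, 2784 lower; 249 at least 2-fold), 5176 at 100 (2568 and 2608) and 5450 at 20 (2750 and 2700). Of 19 NRF2 targets 13 rose, 1 fell and 5 did not pass at 500 µg/mL (13 and 1 adjusted over the list alone; median 0.40, camera adjusted p = 4.47e-09, and adjusted p = 0.183 with an estimated correlation). Fatty acid synthesis had 1 of 14 higher and 9 lower (1 and 11 adjusted over the list alone; median -0.19, adjusted p = 0.000176, and adjusted p = 0.561 with an estimated correlation). Of 13 targets of TGF-beta and YAP, 9 were lower and 4 did not pass (10 lower adjusted over the list alone; median -0.35, adjusted p = 0.000176, and adjusted p = 0.561 with an estimated correlation). AhR targets had 3 of 5 higher (3 adjusted over the list alone; median 0.63, adjusted p = 0.0133, and adjusted p = 0.561 with an estimated correlation). The cholesterol list had 4 of 23 higher and 10 lower and was not called (4 and 12 adjusted over the list alone; adjusted p = 0.0526). From 20 to 500 µg/mL within batch D and within batch E, 1 library per dose each and not tested, its medians were -0.30 (2 of 23 above 0) and -0.26 (1 of 23). Those of fatty acid synthesis were -0.24 (0 of 14) and -0.20 (1 of 14), those of NRF2 targets 0.40 and 0.44 (19 of 19 in both), and those of AhR targets 0.65 (3 of 5) and 0.65 (5 of 5). Targets of TGF-beta and YAP were at -0.18 (0 of 12) and -0.098 (2 of 12). Mitochondrial genome transcripts had 2 of 13 lower beside these (1 adjusted over the list alone; median -0.44, adjusted p = 0.000176, and adjusted p = 0.573 with an estimated correlation). The correlation of the changes with GC content was -0.48. No list of this formula was called with an estimated correlation (0 of 90 tests). Batch E holds all 3 vehicle libraries, and the batch letter alone was called in 40 genes (38 higher in batch D), with 913 at an unadjusted p under 0.05. Without replicate 2, the batch E library, 1887, 1936 and 1443 genes changed at 500, 100 and 20 µg/mL.

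Soyo-san, with 1 library per dose, was compared as values only. From 20 to 500 µg/mL CYP1A1 went from 15.2 to 232 CPM (log2 ratio 3.92, 95% interval 3.76 to 4.08, counting error only), and IGFBP1 from 32 to 96.3 CPM (1.59, 1.46 to 1.71). MT1G went from 54.6 to 17.6 CPM (-1.63), MT1F from 29 to 9.77 CPM (-1.57) and MT1X from 34.6 to 13.6 CPM (-1.34). HMOX1 had a log2 ratio of 0.09, DDIT3 of 0.04 and ALB of -0.16. BOLA2B went from 11.6 to 31.8 CPM (1.46), but it shares reads with a near copy and its level in vehicle was 28 CPM. Among 10000 random lists, the list medians were at percentile 100 for NRF2 targets (0.48, with 18 of 19 above 0), AhR targets (0.70, with 4 of 5 above 0) and glycolysis (0.27, with 14 of 14 above 0). They were at percentile 0 for cholesterol synthesis (-0.40, with 1 of 23 above 0), fatty acid synthesis (-0.36, with 0 of 14 above 0) and metallothioneins (-1.24, with 1 of 7 above 0), and the integrated stress response had a median of 0.005 (percentile 44.5). These percentiles describe the 2 libraries and have no replicate check. Random lists lack the correlation between the genes of a list, and mitochondrial genome transcripts from 20 to 100 µg/mL reached percentile 0 with a small shift (-0.074, with 4 of 13 above 0). Across genes, the log2 ratios correlated with the change from 20 to 500 µg/mL in Yijin-tang (0.43), in Soshiho-tang (0.391) and in the batch D libraries of Okbyeongpung-san (0.175). Against the vehicle libraries, which are all of batch E, CYP1A1 had a log2 ratio of 4.84 at 500 µg/mL.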

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

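The tests chosen after the result was seen were those of the library positions, of growth with dose, of the library code, of the length bias of replicate 3 and of SLC39A10. The comparison of the 2 dose responses below was not among those fixed at the start.

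The change from 20 to 500 µg/mL differed between Soshiho-tang and Yijin-tang in 335 genes (186 higher and 149 lower in Soshiho-tang; 1884 at an unadjusted p under 0.05), by a test of the difference itself. HMOX1, which breaks down heme, differed by 0.672 ± 0.0758 (SE; adjusted p = 8.62e-07). CYP1A1 (-0.55, adjusted p = 0.25), DDIT3 (0.05, adjusted p = 0.919) and ALB (-0.12, adjusted p = 0.472) did not pass, and AhR targets were not called (1 of 7 higher, 2 higher and 1 lower adjusted over the list alone; median difference 0.083, adjusted p = 0.0914).

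Higher in Soshiho-tang on this scale were the metallothionein list (7 of 8 genes called, 8 adjusted over the list alone; median difference 0.999, adjusted p = 4.85e-23), the integrated stress response (10 of 20, 17 adjusted over the list alone; 0.355, adjusted p = 1.29e-23), targets of PXR and CAR (3 of 10, 5 adjusted over the list alone; 0.287, adjusted p = 1.47e-06) and NRF2 targets (9 of 19, 14 adjusted over the list alone; 0.237, adjusted p = 2.48e-19). Cholesterol synthesis (5 of 23, 17 adjusted over the list alone; 0.206, adjusted p = 2.6e-17), fatty acid synthesis (3 of 14, 7 adjusted over the list alone; 0.183, adjusted p = 1.27e-07), autophagy (3 of 15; 0.119, adjusted p = 6.12e-05) and p53 targets (1 of 18; 0.0957, adjusted p = 0.00557) followed. Lower were mitosis genes (9 of 20, 15 adjusted over the list alone; -0.224, adjusted p = 3.23e-16), endoplasmic reticulum chaperones (4 of 18, 10 adjusted over the list alone; -0.197, adjusted p = 2.17e-12) and targets of TGF-beta and YAP (1 higher and 3 lower of 13; -0.0545, adjusted p = 0.0107). Also lower, without a call when the correlation was estimated, were glycolysis (3 of 15; -0.163, adjusted p = 6.21e-08, and adjusted p = 0.0766 with an estimated correlation), hepatocyte identity (2 of 18; -0.119, adjusted p = 5.85e-05, and adjusted p = 0.0678 with an estimated correlation), DNA replication (1 of 22; -0.0712, adjusted p = 0.00123, and adjusted p = 0.0845 with an estimated correlation) and ribosomal proteins (0 of 20; -0.0591, adjusted p = 0.0245, and adjusted p = 0.549 with an estimated correlation).

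The 3 vehicle libraries lay apart from every treated library. With a GC offset per library, 46.97% of the genes called in Soshiho-tang 20 against vehicle stayed called in the same direction (3129 of 6662, of 4456 calls with the offset), between the bounds of 10% and 50% that had been set. Since that decided nothing, library positions were tested. After a GC correction the gap to the nearest treated library was still 1.802 times the largest range within a group (17.1 against 9.48; the gap was 26.4 without correction). This argues against a bias that follows the GC content of the longest transcript as the whole cause. A GC bias of the sequenced fragments that this measure misses was not tested. Genes called at 20 µg/mL in 1 formula moved on from 20 to 500 µg/mL in the other by medians of 12.53% and 6.71% of their size. A response growing with dose needed at least 50% in both, and under 10% in both would have argued against it. Neither bound was met, so growth with dose was not decided. A response already complete at 20 µg/mL stays open too. Separate handling, solvent share or library batch of the vehicle libraries cannot be told apart from such a response, since 0 treated libraries share their code prefix, and changes against vehicle may hold a part that no extract caused.

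Replicate 3 of Yijin-tang at 500 µg/mL lay apart from replicates 1 and 2. Across genes its deviation ran with transcript length (rho -0.3715, and -0.128, -0.493 and -0.682 in the genes of low, middle and high expression), more than in any of the other 20 libraries (up to 0.274), which is what a length bias of that library needs. The value of 0.274 belongs to replicate 2 of the same group, whose comparison mean includes replicate 3. Outside this group the largest in size was -0.151, in vehicle replicate 2. Replicate 3 lay at 85.99% of the distance from the 20 µg/mL libraries to replicates 1 and 2, which argues against a lower effective dose or a mix-up with a library of a lower dose. A candidate explanation is a length bias from library preparation or RNA quality, and no biological explanation was tested.

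Metallothionein genes were lower in Yijin-tang at 500 µg/mL than at 20 µg/mL and than in Soshiho-tang at 500. The summed CPM of 17 MT1 and MT2A genes was 179 ± 18 against 417 ± 29.6 at 20 µg/mL (SD, n = 3 each; log2 difference -1.225, pooled SD 0.125), which argues against reads moved between near copies, and without replicate 3 the list median was -1.254 (-1.19 with it), which argues against the length bias of that library. SLC39A10, a zinc importer gene that is repressed when zinc is plentiful, was higher by 0.8286 in Yijin-tang at 500 against 20 µg/mL and lower in Soshiho-tang than in Yijin-tang at 500 (-0.33 ± 0.0733). Less zinc reaching the cells, for example through binding by extract compounds, is therefore a candidate explanation, as a hypothesis found and tested on the same data. The zinc exporter SLC30A1, which zinc turns on, fell by 0.44 as a member of the same list.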

How the results depend on the processing

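The GC offset, the GC and length offset, the replicate block with the GC offset and the list tests without replicate 3 of Yijin-tang were chosen after the data were seen. Of 437 named gene results, 353 kept direction and side of the threshold under every alternative, single libraries left out included, 82 lost the threshold under at least 1 and 2 reversed. By leaving out single libraries alone, 63 of the 437 lost the threshold without at least 1 library and 0 reversed.

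For Soshiho-tang against Yijin-tang at 20 (8 genes), 19 genes were called without a filter, 13 with DESeq2, 27 with only the groups compared, 14 with the GC and length offset, 13 with block and GC offset, and 4 to 7 with single libraries left out. Soshiho-tang against Yijin-tang at 100 (115 genes) had 195 with only the groups compared, 178 with the GC and length offset and 58 to 71 with single libraries left out. With only the groups compared, a fit with fewer libraries, Soshiho-tang against Yijin-tang at 500 (1239) had 637 and Yijin-tang 500 against 20 (2925) had 1788. The share called higher between the formulas at 500 µg/mL, 50.4%, became 40.2% with the GC offset and 37.2% with the GC and length offset, and for Yijin-tang 500 against 20 µg/mL 54.4% became 65.6% and 69.1%. GC content hardly tracked these changes (rho -0.0155 and -0.0062). The offsets also remove each library's mean log2 deviation across genes, so they change the normalisation as well. Without replicate 3 of Yijin-tang at 500 µg/mL 2151 genes changed from 20 to 500.

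Yijin-tang 20 against vehicle (6538) dropped to 4259 genes with the GC offset, 4102 with the GC and length offset and 4286 with block and GC offset. The GC and length offset gave 4274 for Soshiho-tang 20 against vehicle (6662) and 4597 for Yijin-tang 100 against vehicle (7020). The offset removes a trend with GC content, which these changes followed, and with it each library's mean deviation. At 500 µg/mL of Soshiho-tang ALB reversed to -0.08216, -0.1479 (adjusted p = 0.00189) and -0.08173 under the 3 offset settings. CYP27A1 at 500 µg/mL of Yijin-tang (-0.22) reversed to 0.06003, 0.03793 and 0.06009. Without vehicle replicate 1, ALB at 500 µg/mL of Soshiho-tang was 0.1277 (adjusted p = 0.017).

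With DESeq2 and with the batch E library alone, Okbyeongpung-san 500 against vehicle (5594) gave 3619 and 3352 genes. Okbyeongpung-san 100 against vehicle (5176) gave 3144 and 2478, and Okbyeongpung-san 20 against vehicle (5450) gave 3445 and 3282. With single libraries left out it gave 1887 to 7158, 1936 to 6930 and 1443 to 7132, lowest without replicate 2 and highest without vehicle replicate 1; at 100 µg/mL 3391 were called without replicate 3. Where 1 library stayed in a group it was assumed to vary like the others. Except for the offsets, fewer libraries and fewer or more genes tested, the cause was not tested.

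Among 330 list tests, 55 of 102 calls were lost with an estimated correlation, and fry lost 9 and gained 92. Without replicate 3 of Yijin-tang, 83 of 90 list results stayed the same, 4 gained and 2 lost the threshold. The adjustment ran over these 90 tests alone, which also moves the threshold. Ribosomal proteins between the formulas at 500 µg/mL reversed to a median of 0.0329 (-0.054 with the replicate). For Soyo-san, 1 value, of BOLA2B, moved with other size factors.

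The replicate numbers did not pair the libraries: residuals of 63 pairs with the same number correlated at -0.0819 to 0.0897 (mean 0.0015). With the number as a block, 7957 genes were called for Soshiho-tang 500 against vehicle, 7926 for Yijin-tang 500 against vehicle, 2620 for Soshiho-tang 500 against 20 and 2870 for Yijin-tang 500 against 20.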

Other observations

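NR1H4, the bile acid receptor FXR, fell by 0.65 ± 0.0493 from 20 to 500 µg/mL in Soshiho-tang (SE; adjusted p = 6.99e-12) and by 0.52 ± 0.0484 in Yijin-tang, and ABCB4, which moves phospholipid into bile, fell by 0.55 ± 0.075 and 0.38 ± 0.074. The bile acid list had 3 of 10 lower in Soshiho-tang (3 adjusted over the list alone; median -0.23, camera adjusted p = 0.0103, and adjusted p = 0.05 with an estimated correlation). In Yijin-tang without replicate 3 at 500 µg/mL it had 2 of 10 lower (1 higher and 2 lower adjusted over the list alone; median -0.135, camera adjusted p = 0.0489, and adjusted p = 0.1 with an estimated correlation). Autophagy and lysosome genes had 8 of 15 higher and 2 lower in Soshiho-tang (10 and 2 adjusted over the list alone; median 0.14, adjusted p = 0.000114), with SQSTM1, a cargo receptor and NRF2 target, at 1.19 ± 0.0437, while in Yijin-tang 1 of 15 was higher and the list was not called (adjusted p = 0.303). DUSP6, a phosphatase that ERK signalling turns on, rose by 0.46 ± 0.0579 in Soshiho-tang and 0.33 ± 0.0582 in Yijin-tang, and MYC, a growth regulator, by 0.50 ± 0.0505 and 0.40 ± 0.0506. Immediate early and MAPK targets had 6 of 17 higher in Yijin-tang (6 adjusted over the list alone; median 0.22, adjusted p = 0.00205, and adjusted p = 0.0535 with an estimated correlation) and 4 of 17 in Soshiho-tang (6 adjusted over the list alone; median 0.13, adjusted p = 0.0254, and adjusted p = 0.171 with an estimated correlation). Without replicate 3 of Yijin-tang at 500 µg/mL 5 of 17 were higher in Yijin-tang (6 adjusted over the list alone, median 0.17, adjusted p = 0.00314, and adjusted p = 0.0417 with an estimated correlation). CDKN1A, a cell cycle inhibitor, and MDM2, which degrades p53, rose by 0.31 ± 0.0559 and 0.24 ± 0.0415 in Soshiho-tang, but the p53 list was not called (5 of 18 higher; adjusted p = 0.239).

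Metallothioneins of Soshiho-tang at 500 against 20 µg/mL had 5 of 8 lower (6 adjusted over the list alone; median -0.39, adjusted p = 8.43e-05, and adjusted p = 0.0951 with an estimated correlation). Glycolysis had 6 of 15 higher (6 adjusted over the list alone; median 0.11, adjusted p = 0.000391, and adjusted p = 0.398 with an estimated correlation). Endoplasmic reticulum chaperones in Yijin-tang had 5 of 18 higher and 13 that did not pass (6 higher and 1 lower adjusted over the list alone; median 0.085, adjusted p = 0.0149, and adjusted p = 0.0924 with an estimated correlation). Without replicate 3 of Yijin-tang at 500 µg/mL 4 were higher and 1 lower (median 0.046, adjusted p = 0.0371, and adjusted p = 0.105 with an estimated correlation). Targets of TGF-beta and YAP had 4 of 13 higher and 7 lower in Soshiho-tang (median -0.14, mean 0.081, adjusted p = 0.507) and 1 higher and 4 lower against Yijin-tang at 500 µg/mL (median -0.13, adjusted p = 0.00138), with CCN2, a matrix protein that YAP turns on, at -0.46 ± 0.0577. The lists of heat shock, DNA replication, hypoxia, gluconeogenesis, inflammation, interferon, LXR targets, histones and mitochondrial transcripts were not called between doses in either formula (lowest adjusted p = 0.0749, for heat shock in Yijin-tang). Markers of endothelial cells and leukocytes were not called between doses either (adjusted p = 0.709 and 0.863 in Soshiho-tang, 0.515 and 0.205 in Yijin-tang). In Soyo-san SLC39A10 was at 26.9 CPM at 500 and 15.2 at 20 µg/mL, and the summed metallothionein CPM at 179.2 and 411.

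Each of the 11 comparisons of 3 libraries with 3 was set against the 10 splits of its 6 libraries into 3 and 3, and in each 1 split, the real one, gave as many genes, which is too few splits for a share under 0.05. The real counts were 8002, 6882 and 6662 for Soshiho-tang at 500, 100 and 20 µg/mL against vehicle and 7983, 7020 and 6538 for Yijin-tang. They were 1239, 115 and 8 between the formulas and 2641 and 2925 for 500 against 20 µg/mL. The highest count of another split was 27 for Yijin-tang at 500 µg/mL against vehicle, 1 for the formulas at 500 µg/mL and 0 for the others.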
